A study of Mus musculus with 4 samples.

How the data were processed

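RNA from mouse embryonic fibroblasts was hybridized by the authors to 4 Affymetrix Mouse Genome 430 2.0 arrays, 1 per group: Wip1+/+ and Wip1-/- cells, unirradiated or 4 h after 5 Gy of gamma radiation. The deposited values are signal intensity on a linear scale, 1 value per probe set and array, summarised from the probes by the authors. GCOS, the Affymetrix software, is named without a version in the submitters' processing notes. Its background step, detection calls and scaling target are not given in the sources used here. In each deposited column the mean intensity after trimming 2% at each end was 500, so each array had been scaled to one target. The values were used as deposited, since these trimmed means differed by less than the 5% set as the limit for renormalization. No value was negative or missing, and no column was left out. How far a signal stands over background on a single array sets what can be seen, and the number of arrays limits the precision.

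Probe sets were named by the platform's annotation, with symbols checked by gene identifier against the mouse RefSeq annotation of assembly GRCm38.p6, which changed 0 symbols. Of 45037 probe sets that were not controls, 34945 had 1 symbol and were used. Those with several symbols (932) or not listed (9160) were left out, as they cannot be given to 1 gene. Values under 46.5, the 40th percentile of all values pooled over the arrays, were set to that floor before log2. From 36.7% to 41.7% of probe sets were at the floor on each array. Each gene was represented by its probe set with the highest mean over the 4 arrays, and entered if that mean was at least 67.95, the median of the means of all probe sets. Of 18193 gene symbols, 11546 entered. A fold against a signal at the floor is a lower bound and is written as at least that many fold.

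Comparisons were log2 ratios between pairs of arrays: irradiated over unirradiated in each genotype, and Wip1-/- over Wip1+/+ at each condition. The difference between the irradiation ratios was also taken. With 1 array per group there was no test: genes were counted if they differed at least 2-fold, and no p-value is given. As a measure of error, the SD of the log2 ratio was pooled over genes with several probe sets that passed the filter. It covers differences between probes within a pair of arrays, not those between cultures. Correlations are across genes. Overlaps are given beside the number that independent lists of the same sizes would share. They are also set against lists drawn independently within 20 bins of mean signal, with the central 95% of 10000 draws. This second value was added after the results were seen.

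Gene lists were compiled from textbook knowledge, 30 in all. They held p53 targets, with parts for cell cycle arrest, apoptosis, and repair and metabolism; negative regulators of p53; G2/M, G1/S and DNA repair genes; NF-kB targets; interferon-stimulated genes; immediate early genes; CDK inhibitors and pocket proteins; the integrated stress response; Nrf2 targets; cholesterol synthesis; hypoxia and glycolysis; and ribosomal, housekeeping and mitochondrial respiration genes. Cell type lists were those of fibroblast matrix, myofibroblast and smooth muscle, skeletal muscle, macrophage, endothelial, epithelial, neural, adipocyte, chondrocyte and erythroid genes, and there was a list of sex-linked genes. Each list's median log2 ratio is given with its percentile among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is not a test across cultures.

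Named genes followed a fixed rule. In each comparison these were the 10 highest and 10 lowest log2 ratios of at least 2-fold among genes above the floor on both arrays. Their other probe sets above the floor had to go the same way. The 5 largest bounds in each direction were added, as was every list member at least 2-fold apart or, in a list with none, the 2 largest. All probe sets of Ppm1d and the 10 most positive and 10 most negative response differences were included. Clone and predicted names were passed over. Not every gene so chosen is printed, and list members under 2-fold given as examples were picked after their values were seen. The filter, floor, lists, named-gene rule and the first 9 alternatives below were set before the data were examined.

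Alternatives changed 1 choice at a time: quantile normalization, cyclic loess, scaling by the median of the brighter probe sets, a floor at the 25th percentile, no floor, no filter, a filter at the 67th percentile, the median over a gene's probe sets, and leaving out probe sets whose names end in _x_at or _s_at, which can cross-hybridize. After the data were seen, 2 more were added: a filter at a mean of 500, and the irradiated array labelled Wip1-/- over the mean of both Wip1+/+ arrays, which leaves out the array whose spike-in controls stood apart. R 4.3.3 with limma 3.58.1 was used for normalization, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 for all else. The procedure was tested on simulated data made from the mean signal over the 4 arrays, with noise of SD 0.1 per array on the log2 scale, which is less than the spread between probe sets of the real arrays. All 100 genes given a true 3-fold difference were counted, against 0 of 100 given 1.5-fold and 0 of 11291 left alone. These single genes given a difference were drawn only from those with a mean of 500 or more. The noise was also no wider in dim genes. The simulation therefore does not show how well genes near the floor are called. A list given a true 1.5-fold difference had a median of 0.62 at percentile 100, and an unaltered list ranked at percentile 67.1.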

Results

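Gene expression was measured in mouse embryonic fibroblasts, cells grown out of embryos, on 4 Affymetrix Mouse Genome 430 2.0 arrays. The cells were labelled Wip1+/+ or Wip1-/-. Wip1 is the phosphatase encoded by Ppm1d, known to act on p53 and on kinases of the DNA damage response. For each genotype, 1 array was made from unirradiated cells and 1 from cells harvested 4 h after 5 Gy of gamma radiation. The labels give the unirradiated arrays as 0 h, and no array holds unirradiated cells at 4 h. Effects of radiation and of 4 h of culture therefore cannot be told apart in the irradiation comparisons. Per the series text the arrays were made to examine p53 target genes. Each group held 1 array, so no p-value was computed and no spread between cultures could be measured. The number of arrays limits the precision of every value. The SD of the log2 ratio between probe sets of one gene, is given beside each comparison and does not cover differences between arrays or cultures. Of 45101 probe sets, 64 were controls, and 11546 genes entered the comparisons. The median signal was 72.6 in Wip1+/+ unirradiated, 68.3 in Wip1+/+ irradiated, 85.8 in Wip1-/- unirradiated and 69.5 in Wip1-/- irradiated.

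The unirradiated array labelled Wip1-/- stood apart from the other 3 in its control probe sets. Over the 18 spike-in hybridization controls, bacterial and phage transcripts added to each sample, the SD of the log2 ratio was 0.47, 0.47 and 0.44 in the 3 pairs with this array. It was 0.10, 0.07 and 0.10 in the 3 pairs without it. Against the unirradiated Wip1+/+ array, 5 of the 18 controls differed by at least 1.5-fold, and 0 did in each pair without the array labelled Wip1-/- unirradiated. Across genes, Pearson r of log2 signal was 0.940 to 0.954 in pairs with this array and 0.971 to 0.982 in pairs without it. The 3' over 5' signal ratio of Actb, a measure of RNA integrity, was 1.25 on this array and 1.22 to 1.23 on the others. That of Gapdh was 0.981 on this array and 0.701 to 0.725 on the others. This array enters the irradiation comparison of the cells labelled Wip1-/- and the comparison of unirradiated genotypes.

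**Figure D1:**
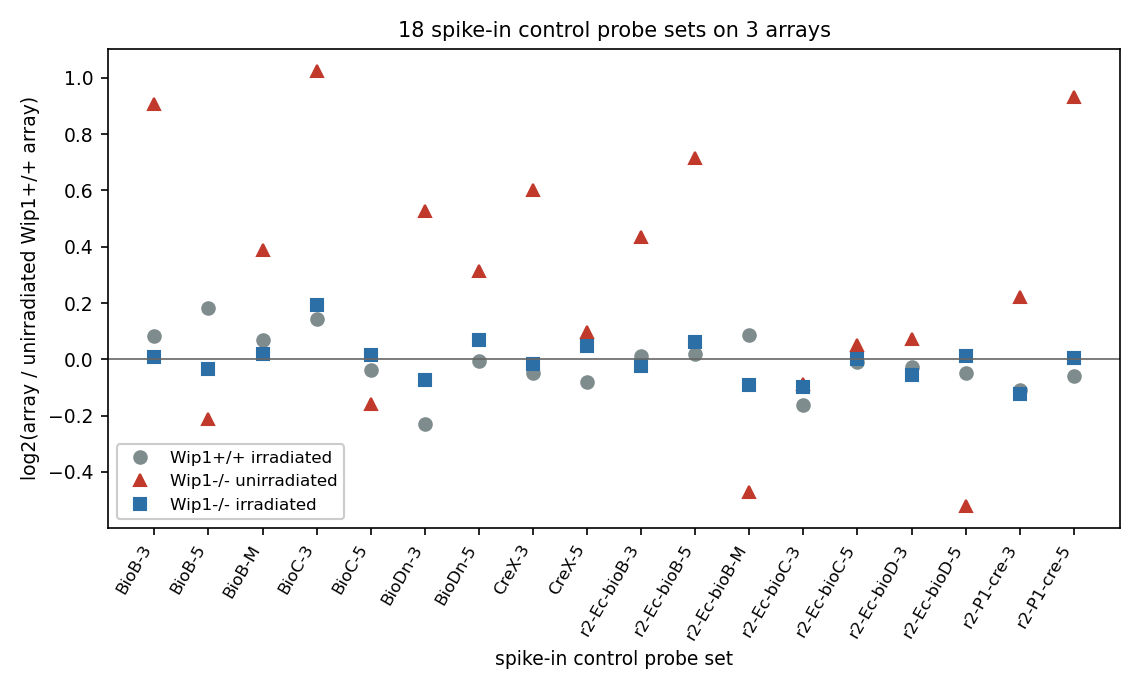
Log2 ratio of the signal of 18 spike-in control probe sets (x axis) on 3 arrays over the unirradiated Wip1+/+ array (y axis), 1 point per probe set and array. The array labelled Wip1-/- unirradiated reached an absolute log2 ratio of 1.02, against 0.23 and 0.19 for the other 2 arrays.

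Ppm1d signal was not lower on both arrays labelled Wip1-/-. The brighter of its 2 probe sets read 375 and 364 in Wip1+/+ cells before and after irradiation, and 504 and 482 in cells labelled Wip1-/-. The other read 317 and 463 in Wip1+/+, and 219 and 561 in cells labelled Wip1-/-. After irradiation it was 1.46-fold higher in Wip1+/+ and 2.56-fold higher on the arrays labelled Wip1-/-. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so the signal does not check the genotype labels. The labels did pair the arrays through other genes. Rpgrip1, which encodes a ciliary protein of photoreceptors, read 6509 and 6854 on the Wip1+/+ arrays and 160 and 176 on those labelled Wip1-/-. This rests on 1 of its 4 probe sets. The others read 48.2 or less on the Wip1+/+ arrays, and 1 of them went the other way. Whether the bright signal comes from Rpgrip1 transcripts was not tested. Cap1, an actin regulator, read 514 and 388 on the Wip1+/+ arrays, against 14875 and 12120 on those labelled Wip1-/-. Both genes are among those with the widest ratios in these data, so they are no independent check of the labels. Because of the Ppm1d signal, the knockout samples are called arrays or cells labelled Wip1-/- throughout.

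Irradiation of Wip1+/+ cells asked which genes differ 4 h after DNA damage when Wip1 is present. Genes known to be activated by p53 were higher as a group. Of 54 measured p53 targets, 43 had a ratio above 1 and 11 below, with a median log2 ratio of 0.27. All 13 measured apoptosis targets were higher, with a median of 0.55. Pidd1, a death domain protein of the p53 pathway, was 3.90-fold higher (90.3 to 352), and Tap1, a peptide transporter of antigen processing, was 2.02-fold higher. These were the only 2 targets past 2-fold. Mitotic and replication genes were lower as groups, by small amounts: 23 of 29 G2/M genes and 18 of 27 G1/S genes had a ratio below 1, with medians of -0.16 and -0.17.

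Among the p53 targets under 2-fold, picked as examples after their values were seen, Fas, a death receptor, was 1.88-fold higher and Btg2, an antiproliferative factor, 1.87-fold. Apaf1, the core of the apoptosome, was 1.80-fold higher, Trp53inp1 1.74-fold and Bbc3, the BH3-only protein Puma, 1.68-fold. Mdm2, the ubiquitin ligase that degrades p53, read 4050 and then 6533, which is 1.61-fold higher. Cdkn1a, the CDK inhibitor of p53-driven arrest, was already among the bright genes without irradiation, at 12735, and read 16318 afterwards, 1.28-fold higher. Its other probe set read 2350 and 2313. Sfn, a 14-3-3 protein of cell cycle arrest, had a log2 ratio of -0.41, and Ddb2, a damage sensor of nucleotide excision repair, one of -0.36. The arrest targets had a median of 0.29, those of repair and metabolism 0.20 and the negative regulators of p53 0.25. Among 10000 random lists matched on signal, the median of the whole p53 list and that of its apoptosis part ranked at percentile 100. The arrest part ranked at 99.92, repair and metabolism at 99.2 and the negative regulators at 99.8. Gadd45a, a p53-responsive growth arrest gene outside the lists and chosen after its values were seen, was higher after irradiation in both genotypes, with log2 ratios of 1.29 and 1.18.

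Immediate early genes were higher as a group in irradiated Wip1+/+ cells. Egr1, an immediate early transcription factor, read 1617 and then 3701, 2.29-fold higher. Fos, an early response transcription factor, was 2.00-fold higher, and 13 of 19 immediate early genes had a ratio above 1, with a median of 0.24 at percentile 99.98. Chac1, a glutathione-degrading enzyme of the integrated stress response, was 2.56-fold higher (440 to 1125), while of 14 genes of that response 8 had a ratio above 1 and 6 below, with a median of 0.22 at percentile 99.98. Lig4, the ligase of end joining, was 2.10-fold higher, while the DNA repair list as a whole had a median of -0.08 at percentile 5.86. Among mitotic genes Nek2, Prc1 and Plk1 had log2 ratios of -0.63, -0.53 and -0.51, but other probe sets of Nek2 and Prc1 had -0.12 and -0.02. Among replication genes Mcm2, a helicase subunit, had one of -0.80, and its other probe set -0.28. Both cell cycle medians ranked at percentile 0.

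Hypoxia and glycolysis genes had a median of 0.10 at percentile 98.6, and Nrf2 targets of the oxidative stress response 0.15 at 97.1. All 9 CDK inhibitors and pocket proteins had a ratio above 1, with a median of 0.15 at percentile 90.8. The medians of NF-kB targets, interferon-stimulated genes and macrophage markers were -0.02, -0.03 and -0.05. Fibroblast matrix genes had a median of -0.03, myofibroblast genes -0.10 and endothelial markers -0.34 at percentile 2.52. Control groups lay near 0, with medians of -0.07 for ribosomal proteins, 0.03 for housekeeping genes and -0.03 for mitochondrial respiration. The signs of the ribosomal, mitochondrial and fibroblast matrix medians turned under quantile normalization and cyclic loess.

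By the fixed rule of size, 182 genes were at least 2-fold higher and 173 at least 2-fold lower after irradiation of Wip1+/+ cells. Scaling by the median of the brighter probe sets gave 170 and 177. The SD between probe sets was 0.37, and 0.18 among genes with a mean signal of 500 or more. Most of these genes were dim: 153 of the 182 and 159 of the 173 had a mean signal under 200. The 3 genes with a mean of 500 or more that were higher were Chac1, Egr1 and 9230114K14Rik, and the 2 that were lower were Fbxo36 (log2 ratio -1.12) and Serpinb6e (-1.07). These were named after their values were seen. After Pidd1, the named genes with the highest ratios were Ero1b, an oxidoreductase of the endoplasmic reticulum (3.73-fold), Dusp8, a MAP kinase phosphatase (3.72-fold), Rhbdf2 (3.70-fold), Zfp994 (3.54-fold), B3galt4 (3.51-fold) and Trp53rka (3.45-fold). Trim7, Rgs1 and Zfp518a followed at 2.89-, 2.85- and 2.82-fold. The lowest were H2bc22, a histone gene (5.90-fold lower), Il17re, a receptor chain (4.04-fold), Sncb, a synuclein (3.78-fold), and Rpl39, a ribosomal protein (3.53-fold). Tmem171, Tlx2, Popdc2, Rsph9, Spef1 and Oosp3 were 2.61- to 2.89-fold lower. Against a signal at the floor, Pkp1, a desmosome protein, was at least 4.68-fold higher, and Slc22a16, Ddx25, Apobec1 and Tex15 were at least 3.55- to 3.96-fold higher. Clip4 was at least 5.69-fold lower, and Dnase2a, Cxcl17, Pam and Sarm1 were at least 3.86- to 4.78-fold lower. Of the 30 genes named by this rule, 5 had another probe set above the floor on at least 1 of the 2 arrays, and in all 5 one was opposite or under 2-fold. These were Ero1b, with log2 ratios of -0.23 and -0.17 by its other probe sets and 0.84 by the median over all, Dusp8 with 0.28, Trim7, Clip4 and Sarm1.

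Irradiation of cells labelled Wip1-/- asked whether the damage response differs without Wip1. The p53 targets were again higher as a group: 38 of 54 had a ratio above 1, with a median log2 ratio of 0.22 at percentile 99.6. Pidd1 was 2.88-fold higher, and 6 further targets passed 2-fold. These were Rprm, a factor of G2 arrest (2.49-fold), Ccng1, cyclin G1 (2.29-fold), Bbc3 (2.29-fold), Trp53inp1 (2.19-fold), Polk, a translesion polymerase (2.17-fold), and Fbxw7, a ubiquitin ligase subunit (2.02-fold). A second probe set of Fbxw7 had a log2 ratio of -0.02, and the third of Ccng1 one of 0.18, with signals of 12785 and 14518. Across both genotypes, 32 of the 54 targets had a ratio above 1 in each and 5 a ratio below 1 in each. The unirradiated array of this comparison is the one whose spike-in controls stood apart.

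Individual targets differed from the Wip1+/+ values. Fas and Plk3 had log2 ratios of -0.40 and -0.78 here, against 0.91 and 0.29 in Wip1+/+ cells. The probe sets of Apaf1 disagreed: one had -0.17 here against 0.84, and the other 0.81 against 0.98. Those of Ccng1 did too, with 1.20 against 0.16 by the brightest and 0.18 against 0.08 by another. Btg2 was alike in both, at 0.93 and 0.91. Cdkn1a read 8920 and then 15476, with a log2 ratio of 0.79, and Mdm2 5777 and then 6285. The other bright probe set of Mdm2 read 3006 and 5179, and in Wip1+/+ cells 3088 and 4771. The 13 apoptosis targets had a median of 0.43 at percentile 99.1, with 9 above 0, and the 9 arrest targets 0.39 at percentile 97.0. Targets of repair and metabolism had a median of 0.05, whose sign turned when arrays were scaled by the median of the brighter probe sets. The negative regulators of p53 had a median of 0.22 at percentile 86.2. The SD of the matched random medians was 0.21 here, against 0.07 in Wip1+/+ cells.

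**Figure D2:**
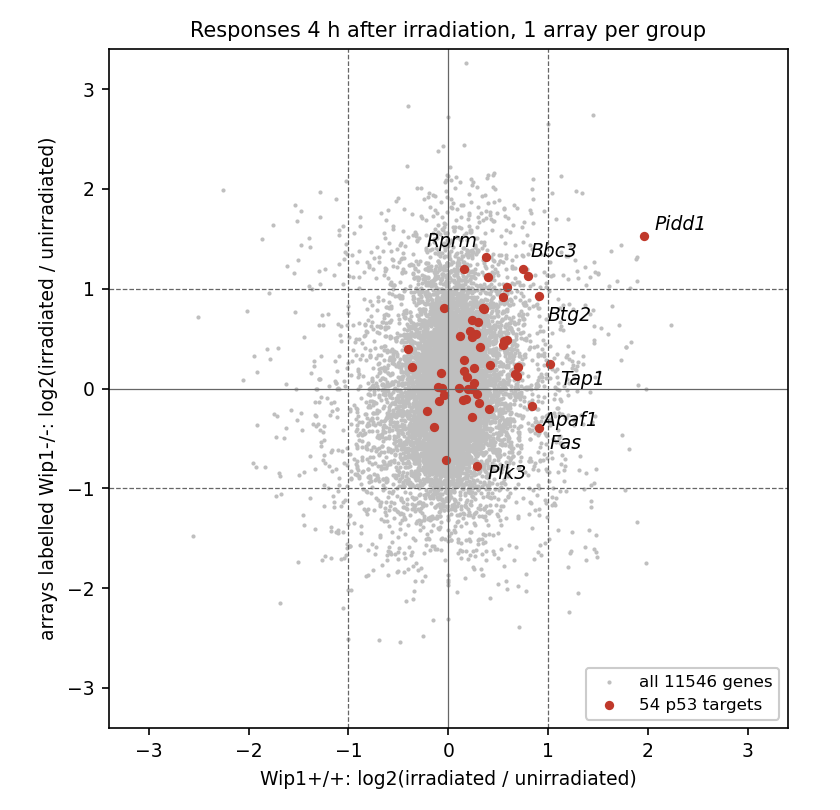
Log2 ratio of irradiated over unirradiated signal in Wip1+/+ cells (x axis) and on arrays labelled Wip1-/- (y axis) for 11546 genes, with 54 p53 targets in red. Pidd1 lay past 2-fold on both axes (dashed lines), and 32 of the 54 targets had a ratio above 1 on both.

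Cell cycle groups did not stand out on these arrays, but medians of random lists spread more widely here. Their SD was 0.119 for G2/M genes and 0.122 for G1/S genes, against 0.047 and 0.051 in Wip1+/+ cells. The Wip1+/+ medians of -0.155 and -0.173 would lie within the central 95% here, -0.238 to 0.225 and -0.231 to 0.246. A response of that size would thus not stand out, and percentiles cannot be compared between the genotypes. G2/M genes had a median of -0.07 at percentile 33.7, and G1/S genes 0.03 at 59.5, with a sign that turned under cyclic loess and brighter-median scaling. Mcm2 and Mcm3, helicase subunits, were 2.36- and 2.64-fold higher, but the other probe set of Mcm2 had a log2 ratio of -0.21 and the other 4 of Mcm3 lay between -0.36 and 0.26. Fos was at least 6.27-fold higher and Fosl1, another early response factor, 2.31-fold, while Nr4a1, an immediate early nuclear receptor, was 2.31-fold lower. The immediate early list had a median of 0.01. Interferon-stimulated genes had a median of 0.30 at percentile 97.8, with Irf9, a subunit of the interferon response factor, 2.19-fold higher and Oas1a, which makes an antiviral second messenger, at least 3.44-fold higher. Iigp1, of the same list, went the other way, with a log2 ratio of -1.25 or below, against 0.28 by another probe set. Random lists were matched on the mean over all 4 arrays, but most interferon-stimulated genes were dimmer on the arrays labelled Wip1-/-. Usp18, for one, had a mean of 701 but read 80.9 and 121.5 here. The percentile thus sets these genes against genes that were brighter on these arrays. Contractile genes of myofibroblasts had a median of -0.48 at percentile 0.6, and matrix genes -0.33 at percentile 3.12. NF-kB targets had a median of -0.30 at percentile 5.62. Other medians lay within the central 95% of random lists, among them 0.09 for the integrated stress response, -0.11 for DNA repair, 0.20 for cholesterol synthesis and -0.15 for hypoxia and glycolysis.

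On the arrays labelled Wip1-/-, 658 genes were at least 2-fold higher and 534 lower after irradiation, with an SD between probe sets of 0.62. Scaling by the median of the brighter probe sets gave 554 higher and 700 lower. Among genes with a mean of 500 or more, 221 were higher and 54 lower. Named genes with the highest ratios were mostly low on the unirradiated array alone. Psmc4, an ATPase of the proteasome, read 1550 there and 7203 after irradiation, against 6604 and 6699 in Wip1+/+, and its other probe set read 3644 and 4264. Kbtbd13 was 5.42-fold higher, and Ythdc2, Btbd2, Ptger4 (a prostaglandin receptor), Pknox2, Top3b (a topoisomerase), Rgs3, Fam25c and Sec11c were 3.95- to 4.38-fold higher. With probe sets prone to cross-hybridization left out, Top3b had a log2 ratio of 0.20. The lowest ratios were those of Pax5, a B cell transcription factor (5.24-fold lower), and Ung, the uracil-DNA glycosylase (4.97-fold lower). Cep70, Ammecr1, Sigirr, Kcnq1, Gdf11, Cntn1, Sox10 and Tlx3 were 3.58- to 4.05-fold lower. As bounds, Slc25a25 was at least 7.13-fold and Kptn at least 6.71-fold higher, Hif3a and Zbtb40 at least 4.69- and 4.46-fold higher, and Echdc3, Treml1, Cphx3, Rcor2 and Slc52a3 at least 4.58- to 5.73-fold lower. Of the 2 dimmer probe sets of Slc25a25, one was lower after irradiation, at 109 and 19.7, and one higher, at 13.4 and 117. That of Kptn was lower, at 74.2 and 38.9. In 13 of the 14 named genes with another probe set above the floor, one was opposite or under 2-fold. Besides those given, these were Pknox2 (log2 ratio 0.67), Rgs3 (0.10), Sec11c (-0.23), Cep70 (-0.29), Pax5 (-0.33), Sox10, Ammecr1, Hif3a and Cphx3.

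The comparison of unirradiated genotypes asked which genes differ without Wip1 before damage. Macrophage markers and interferon-stimulated genes were lower on the array labelled Wip1-/-. All 15 macrophage markers had a ratio below 1, 10 of them by at least 2-fold, with a median log2 ratio of -1.76. Ctss, a lysosomal protease of phagocytes, was 10.6-fold lower, and Lyz2, lysozyme, 5.04-fold lower. Of 20 interferon-stimulated genes, 18 had a ratio below 1 and 14 were at least 2-fold lower, with a median of -1.58. Usp18, the protease that removes Isg15, was 17.2-fold lower and Bst2, tetherin, 8.40-fold lower. Both medians ranked at percentile 0. The array labelled Wip1-/- here is the one whose spike-in controls stood apart.

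Inflammatory NF-kB targets went the other way as a group, with 12 of 18 above 0 and a median of 0.59 at percentile 99.94. Cxcl5, a neutrophil chemokine, was 2.93-fold higher, Il6, an inflammatory cytokine, 2.34-fold and Ccl7, a monocyte chemokine, 2.25-fold higher. Icam1, an adhesion molecule, was at least 3.33-fold lower, and Nfkb2, an NF-kB subunit, 2.69-fold lower, with a log2 ratio of -0.74 by its other probe set. The p53 targets had a median of -0.08 at percentile 8.23, and no member was at least 2-fold higher. Sfn was at least 3.82-fold lower, Rprm 2.93-fold, Perp, a p53 effector in cell adhesion, 2.68-fold, and Ccng1 2.09-fold lower, though the third probe set of Ccng1 had a log2 ratio of -0.10. Arrest targets had a median of -0.41, apoptosis targets -0.07, targets of repair and metabolism -0.10 and negative regulators -0.18. DNA repair genes had a median of 0.32 at percentile 98.1, with Ung 2.45-fold and Lig4 2.33-fold higher. Among replication genes with a median of -0.15, Mcm3, Mcm6 and Ccne1, cyclin E1, were 2.46-, 2.26- and 2.05-fold lower by their brightest probe sets. The next of Mcm6 was higher, at 924 and 1786, the others of Mcm3 had log2 ratios of -1.10 to -0.14, and that of Ccne1 one of -0.43. The G2/M median was 0.07.

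Sex-linked genes differed between the labels, which give no sex for the embryos. Kdm5d and Uty, both on the Y chromosome, were at least 2.56-fold and 2.11-fold lower, and Xist, the X inactivation transcript, had a log2 ratio of -0.26. Other probe sets, each with a signal at the floor, had log2 ratios of 0.04 for Kdm5d and of -0.98 and 0.65 for Uty. Markers of other cell types had medians of 0.61 for epithelial cells at percentile 96.5, 0.33 for endothelium, 0.42 for skeletal muscle and 0.44 for chondrocytes. Those of neural cells and adipocytes were -0.32 and -0.44. Dsp, desmoplakin, was 3.69-fold higher among the epithelial markers, and its other probe sets had log2 ratios of 0.88 and 0.62. In the neural list Map2, a microtubule protein of neurons, was 5.46-fold higher and Tubb3, a neuronal tubulin, 4.13-fold lower. Matrix genes had a median of 0.35 at percentile 96.6 and contractile genes 0.24. None of the 8 erythroid markers could be measured, as 6 were below the filter and 2 had no probe set named here.

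Between the unirradiated arrays 593 genes were at least 2-fold higher and 789 lower with the Wip1-/- label, and 101 and 269 with a mean of 500 or more. Scaling by the median of the brighter probe sets gave 738 higher and 692 lower, so which direction held more genes depends on the scaling. The SD between probe sets was 0.65. The highest ratios were those of Erdr1 at 29.3-fold, Cap1 at 28.9-fold, Tmem87a at 14.5-fold and Rbm45, an RNA-binding protein, at 9.18-fold. Clec16a, Mgll (monoacylglycerol lipase), Pdgfrl, Gbe1 (glycogen branching enzyme) and Treml1 were 4.67- to 6.92-fold higher. The lowest, after Usp18 and Rpgrip1 at 40.8-fold, included Rtp4, an interferon-induced chaperone (10.4-fold lower), Apoe, an apolipoprotein of macrophages and other cells (9.04-fold), and Lyz1 (8.11-fold). Ngdn, Mfsd3 and Snhg6 were 8.64-, 5.69- and 5.55-fold lower. The other probe set of Ngdn read 1053 and 776. As bounds, Ifi202b, an interferon-inducible gene, was at least 11.9-fold higher, and Pax5, Acp5, Fxyd6 and Iqgap2 at least 5.50- to 5.63-fold higher. Xaf1 was at least 32.7-fold lower, though its dimmer probe set read 38.7 and 393, in the opposite direction. Ang, angiogenin, was at least 18.0-fold lower, but its log2 ratio was -0.80 without probe sets prone to cross-hybridization. Ifit1, Micu3 and Ahi1 were at least 6.78- to 7.48-fold lower. In 9 of the 12 named genes with another probe set above the floor, one was opposite or under 2-fold. Besides Xaf1, Ngdn, Ang and Rpgrip1, these were Ahi1 (log2 ratio -0.22), Lyz1 (1.59), Erdr1, Pax5 and Iqgap2.

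The comparison of irradiated genotypes asked the same 4 h after damage, with ratios that leave out the array that stood apart. That array still counted in the floor, the filter and the choice of probe sets. Macrophage markers and interferon-stimulated genes were again lower with the Wip1-/- label. All 15 macrophage markers had a ratio below 1, 13 by at least 2-fold, with a median of -1.68. Lyz2 read 4986 in Wip1+/+ and 673 in cells labelled Wip1-/-, 7.41-fold lower, and Csf1r, the receptor that macrophages need to survive, was 2.30-fold lower, with log2 ratios of -0.88 and -0.89 by other probe sets. Of the 20 interferon-stimulated genes, 19 had a ratio below 1 and 14 were at least 2-fold lower, with a median of -1.10. Usp18 was 9.93-fold lower, and Ifih1, a sensor of viral RNA, 4.06-fold lower. In both genotype comparisons together, 10 macrophage markers and 10 interferon-stimulated genes were at least 2-fold lower in each.

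**Figure D3:**
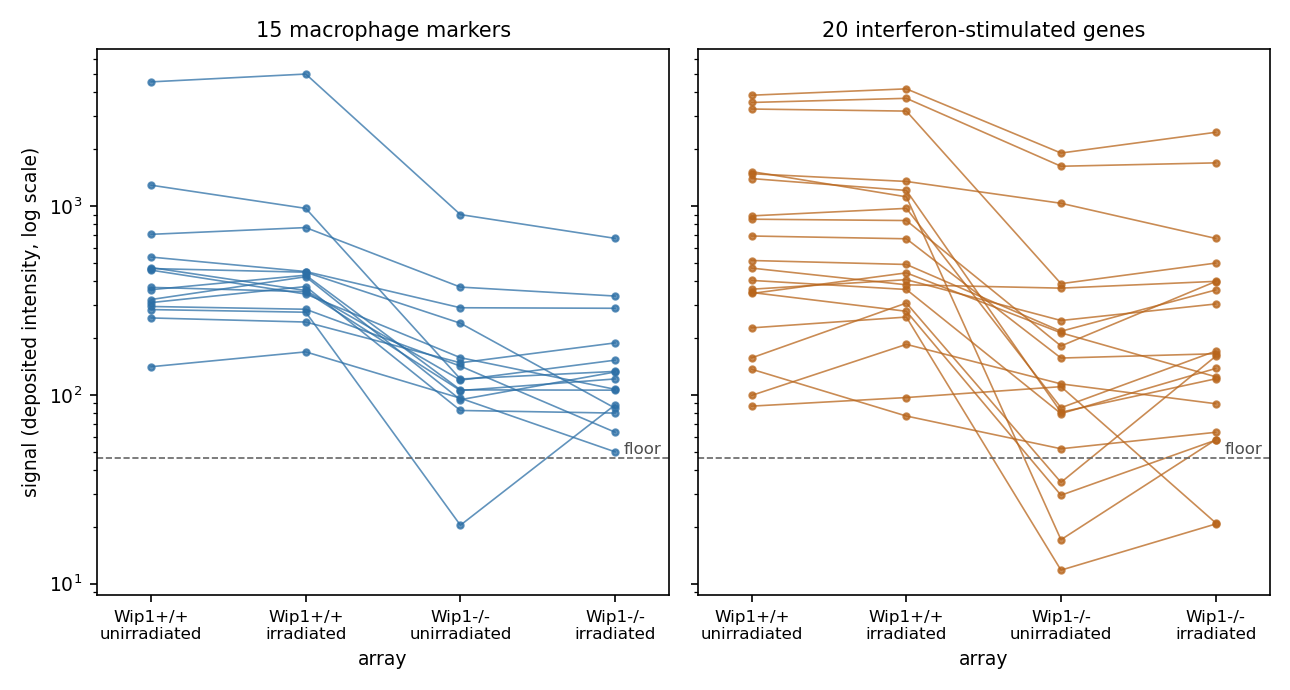
Signal (deposited intensity, log scale) on the 4 arrays of 15 macrophage markers, left, and 20 interferon-stimulated genes, right, 1 line per gene, with the floor of 46.5 dashed. All 15 macrophage markers and 17 of the interferon-stimulated genes were lower on the array labelled Wip1-/- in both the unirradiated and the irradiated pair.

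NF-kB targets were again higher in 12 of 18, with a median of 0.26 at percentile 99.7. Cxcl5 and Cxcl1, both neutrophil chemokines, were 2.31- and 2.07-fold higher, with 0.25 as the lowest log2 ratio among probe sets of Cxcl1, whereas Icam1 was 2.49-fold and Saa3, an acute phase protein, at least 3.97-fold lower. The p53 targets had a median of -0.10 at percentile 0.15, with 35 of 54 below 0. Against the mean of both Wip1+/+ arrays, 1 of them unirradiated, this median was 0.06. A control list, the housekeeping genes, had a median of -0.14 at percentile 0.43 between the irradiated arrays, so a shift of this size was not particular to p53 targets. At least 2-fold lower among the p53 targets were Fas (2.57-fold), Tap1 (2.22-fold), Sfn (2.19-fold) and Perp, with a log2 ratio of -1.32. The arrest targets had a median of -0.28, the apoptosis targets -0.14, and the targets of repair and metabolism -0.08. G2/M genes had a median of 0.11 at percentile 98.7, with Nek2, a mitotic kinase, 2.83-fold higher by its brightest probe set. The next of Nek2 was lower, at 152 and 112. G1/S genes had a median of 0.05, and Mcm2 was 2.34-fold higher by one probe set and had a log2 ratio of 0.03 by the other.

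Nrf2 targets had a median of -0.21 at percentile 0.87, with no member past 2-fold. All 6 measured epithelial markers were higher, with a median of 0.56 at percentile 99.6. Dsp was 2.02-fold higher, with log2 ratios of 0.36 and -0.06 by its other probe sets, and Epcam, an epithelial adhesion molecule, at least 4.19-fold higher. Endothelial markers had a median of 0.45 at percentile 98.5, although Emcn, an endothelial sialomucin, was 2.07-fold lower. The neural list had a median of -0.32 with Map2 6.64-fold higher. Among sex-linked genes Kdm5d, Uty and Eif2s3y, all on the Y chromosome, were 2.37-fold, at least 2.25-fold and 2.17-fold lower, while Xist had a log2 ratio of 0.40. Another probe set of Kdm5d had a log2 ratio of -0.17, and another of Uty one of -1.20. Housekeeping genes had a median of -0.14 at percentile 0.43. Medians of the other lists lay within the central 95% of random lists, from -0.17 in skeletal muscle to 0.17 in adipocytes.

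Between the irradiated arrays 271 genes were at least 2-fold higher and 340 lower with the Wip1-/- label, with an SD between probe sets of 0.41. With a mean of 500 or more the counts were 33 and 51. Cap1 was 31.2-fold and Rbm45 9.76-fold higher, and Pdgfrl and Mgll 5.32- and 4.76-fold higher. Atp10d, Il17re, Thg1l, Oip5 and Cd200, a ligand that restrains myeloid cells, were 4.11- to 7.37-fold higher. Rpgrip1 was 39.0-fold lower, Xaf1 19.3-fold, Ang 11.9-fold, Ctss 7.29-fold, Bst2 6.38-fold and Lyz1 6.14-fold lower. The value of Lyz1 again came from a probe set prone to cross-hybridization. Qpct, which caps peptides with pyroglutamate, was 7.76-fold and Amacr, a racemase of fatty acid breakdown, 6.70-fold lower. The second probe set of Xaf1 read 34.5 and 640, in the opposite direction. As bounds, Tmem87a, Ptprv, Ifi202b, Clip4 and Pam were at least 5.80- to 17.1-fold higher. Zfp874a, the macrophage chemokine gene Ccl6, Plxnb3, Clec4d (a myeloid lectin) and the interferon-inducible GTPase Igtp were at least 6.06- to 8.77-fold lower. In 9 of the 12 named genes with another probe set above the floor, one was opposite or under 2-fold. Besides Xaf1 and Rpgrip1, these were Ang, with a log2 ratio of -0.68 without probe sets prone to cross-hybridization, Il17re (0.44), Thg1l (0.85), Lyz1 (-0.34), Mgll, Clip4 and Plxnb3.

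The responses of the genotypes were compared directly, since the irradiation ratios share no array. No common difference stood out among the p53 targets: the median of the Wip1-/- minus the Wip1+/+ log2 ratio was -0.02 at percentile 52.95. The central 95% of matched random lists ran from -0.213 to 0.14. A difference within that range would not stand out, while the whole median response of these targets in Wip1+/+ cells was 0.27. G1/S genes had a median difference of 0.28 at percentile 99.1, interferon-stimulated genes 0.41 at 99.5, immediate early genes -0.35 at 1.88 and fibroblast matrix genes -0.42 at 0.21. Each of these differences takes in the array whose spike-in controls stood apart. The percentile of the interferon-stimulated genes also rests on random lists of genes that were brighter than they were on the arrays labelled Wip1-/-. Above the floor on all 4 arrays, the most positive differences were those of Wnt6, a secreted signalling protein, at 3.02, Il17re at 2.79, St3gal6 at 2.69, Pcp4l1 at 2.48 and Angpt1, angiopoietin, at 2.41. Mab21l2, Usp13, Syne3, Fndc4 and Kbtbd13 followed at 2.28 to 2.40. The most negative were Dusp8 at -3.23, Arhgef6 at -2.99, Gbe1 at -2.95, Depp1 at -2.87 and Sigirr, a brake on interleukin signalling, at -2.68. Dhh, a hedgehog ligand, Ammecr1, H2-Ke6, Sec14l3 and B3galt4 lay between -2.61 and -2.42. In 9 of the 10 of these genes with another probe set above the floor on at least 1 array, one gave an opposite difference or one under 1. Opposite were Usp13 (-1.32), Wnt6 (-0.96) and Il17re (-0.84). Smaller were Dusp8 (-0.34), Fndc4 (0.76), St3gal6 (0.09), Depp1, Ammecr1 and Sec14l3.

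Across 11546 genes, which are not independent replicates, the irradiation responses had a Pearson r of 0.09 and a Spearman rho of 0.10. Among the 6398 genes with a mean of 500 or more r was 0.12. Genes at least 2-fold higher in both numbered 36, against 10.4 for independent lists and 19.4 for lists independent among genes of like signal (central 95% 12 to 27). Those lower in both also numbered 36, against 8 and 29.1 (20 to 38), so this overlap did not pass what dim genes give by chance. With a mean of 500 or more, 1 was higher in both and 0 lower. Genes chosen as at least 2-fold higher in Wip1+/+ cells had a median log2 ratio of 0.08 in cells labelled Wip1-/-, and those chosen as lower one of -0.21. The genotype ratios of the unirradiated and irradiated pairs had an r of 0.32 and a rho of 0.21, or 0.42 and 0.22 at a mean of 500 or more. In both pairs, 91 genes were at least 2-fold higher, against 13.9 for independent lists and 32.1 among genes of like signal (22 to 42). Lower in both were 148, against 23.2 and 37.0 (26 to 48). With a mean of 500 or more, 21 were higher in both and 36 lower.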

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

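Of the tests in this part, those on the array that stands apart, on the macrophage markers and on the interferon-stimulated genes were all chosen after the results were seen.

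Between the unirradiated arrays, 5 of the 18 spike-in controls, which no comparison uses, were at least 1.5-fold apart, against 0 in the pairs without the array labelled Wip1-/- unirradiated. A technical difference of that array may account for its distance from the other 3. The lowest SD over spike-in controls in pairs with it was 4.25 times the highest in pairs without it, and cells contribute nothing to these controls. The genotype alone could not be judged as the reason for the distance across genes. Of the genes at least 2-fold apart between the unirradiated arrays, 17.3% were so in the same direction between the irradiated arrays. That is under the limit set for the genotype alone. However, 394 of the 593 higher and 347 of the 789 lower genes had a mean signal under 200. Noise in dim genes, or a genotype effect that irradiation changes, would also lower the share. Degraded RNA could not be excluded: the log2 3' over 5' ratio of Actb was 0.031 above the median of the other arrays, but that of Gapdh was 0.46 above it. Spike-in controls do not come from the cells, so they cannot show whether cell RNA was degraded. Their probe sets for 3' and 5' ends kept together in some pairs on this array and not in others. Against the unirradiated Wip1+/+ array, a pair of BioC had log2 ratios of 1.02 and -0.16, and a pair of Cre 0.22 and 0.93. Closer together were another pair of BioC, at -0.09 and 0.05, and one of BioDn, at 0.53 and 0.31. Probe sets for the same 3' end of BioC thus disagreed on this array, at 1.02 and -0.09. Whether the culture differed as well stays open, so single genes of the irradiation response on the arrays labelled Wip1-/- cannot be ascribed to the genotype.

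Macrophage markers were lower with the Wip1-/- label. A technical difference of the unirradiated array was excluded as the reason, since the median was -1.68 between the irradiated arrays, which do not include it, and lay below all matched random lists. Fewer macrophages in the cultures labelled Wip1-/- stays open and was not tested, because the count of 15 of 15 markers lower in both genotype comparisons restates the pattern. None of the 15 markers stands in another list used here, but how many of them fibroblasts also express was not measured. No sort that would remove such cells is given in the labels. The brightest marker, Lyz2, read 4533 and 4986 in Wip1+/+, and 899 and 673 in cells labelled Wip1-/-, so a signal was left in the latter. Whether this follows from the genotype or from embryos and cultures that happened to differ was not tested, since each genotype may rest on 1 culture.

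Interferon-stimulated genes were lower with the same label. Loss of macrophage RNA alone could not be excluded as the reason: between the irradiated arrays, 2 of these genes were lower by more than the most reduced macrophage marker by over 1 SD of probe sets, a limit of -3.30. These were Xaf1 and Usp18, and the other probe set of Xaf1 went in the opposite direction. At least 3 such genes would have been needed to exclude it. A lower interferon response of the fibroblasts themselves stays open and was not tested.

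Other genes were flagged because irradiation moved the arrays of the genotypes at least 2-fold in opposite directions, which 58 genes did. This count was not set against what dim genes give by chance. Under a mean signal of 200 lay 153 of the 182 genes higher and 159 of the 173 lower in Wip1+/+. With the Wip1-/- label these were 298 of 658 and 417 of 534. The differences of the 58 genes were not tested, and each includes the array that stands apart. Given as the Wip1-/- minus the Wip1+/+ log2 ratio, the positive ones among the named genes were Wnt6 at 3.02, St3gal6 at 2.69, Pcp4l1 at 2.48, Angpt1 at 2.41, Usp13 at 2.37 and Fndc4 at 2.34. In other probe sets, Wnt6 had an opposite difference of -0.96, and Dusp8 and Fndc4 smaller ones of -0.34 and 0.76. The second probe set of Usp13 went the other way, at 135 and 128 on the Wip1+/+ arrays and 123 and 18.0 on those labelled Wip1-/-. The negative ones were Dusp8 at -3.23, Arhgef6 at -2.99, Gbe1 at -2.95, Depp1 at -2.87, Dhh at -2.61, H2-Ke6 at -2.52 and Sec14l3 at -2.52. With signals at the floor, the differences were bounds in other genes: at least 4.25 in Dnase2a, 2.84 in Epcam and 2.42 in Spef1, and -3.73 or below in Ddx25, -3.45 in Rcor2 and -2.67 in Saa3.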

How the results depend on the processing

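The filter at a mean of 500 and the comparison with the mean of both Wip1+/+ arrays were chosen after the data were seen; the other 9 alternatives were planned. No replicate could be left out with 1 array per group. Of the counts, 62 stayed within 1.5 times their value and 20 did not. Without a filter, 281 genes were lower after irradiation of Wip1+/+, 953 lower after irradiation with the Wip1-/- label and 1016 higher between unirradiated genotypes, as more dim genes enter by construction. The filter at the 67th percentile gave 20 higher and 8 lower after irradiation of Wip1+/+, 337 and 100 with the Wip1-/- label, 181 and 411 between unirradiated and 62 and 96 between irradiated genotypes. At a mean of 500 these were 3 and 2, 221 and 54, 101 and 269, and 33 and 51. Both filters leave fewer genes, 8507 and 6398. The median over probe sets gave 437 higher after irradiation with the Wip1-/- label; the cause was not tested.

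Of the list medians, 1333 stayed within their spread, 143 moved and 3 reversed. The sex-linked median between irradiated genotypes was 0.40 under both stricter filters, because only Xist was left. The p53 target median between irradiated genotypes was 0.056 against the mean of both Wip1+/+ arrays, 1 of which is unirradiated by construction. Over all alternatives run, the median of macrophage markers between irradiated genotypes stayed between -1.72 and -1.63, or -2.87 at a mean of 500, where 3 of the 15 are left, and that of interferon-stimulated genes between -1.26 and -1.04, or -1.82 with 8 of the 20 left at that mean. Scaling by the brighter probe sets shifted the median of all genes to -0.12 for irradiation with the Wip1-/- label and 0.12 between unirradiated genotypes. Ppm1d (18 values) and the correlation of responses (10) did not move beyond their spread. Of values for named genes, 1098 stayed and 86 moved. Past 2-fold no longer were Ero1b (0.84), Top3b (0.79) and Xaf1 (-0.98 unirradiated, -0.24 irradiated) by the median over probe sets, and Ang (-0.80, -0.68), Ngdn (-0.44) and Top3b (0.20) without cross-hybridizing probe sets. No value could be had for 111 named results at a mean of 500, 92 at the 67th percentile, 12 without cross-hybridizing probe sets and 1 under cyclic loess. Signal over background limits the rest: most genes past 2-fold after irradiation of Wip1+/+ lie under a mean of 200, where a ratio rests on values near the floor.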

Other observations

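The tests on strain DNA in this part were set before their results were seen; the genes named here outside the lists were chosen after.

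Single myeloid and interferon-inducible genes outside the fixed lists were picked from the genes lower in both genotype pairs, so they are no test of such genes as a group. Log2 ratios of the Wip1-/- over the Wip1+/+ label, unirradiated and then irradiated, were -2.00 and -2.07 for Fcgr3, a receptor for antibodies, and -1.81 and -2.67 for C3ar1, a complement receptor. They were -2.04 and -2.10 for Ms4a7, a membrane protein of macrophages, and -1.36 and -2.18 for Ccl9, a chemokine. Cd36, a scavenger receptor counted here with the adipocyte markers, was at least 5.84- and 5.20-fold lower. Among interferon-inducible genes, Irgm2, an immune GTPase, had ratios of -2.28 and -1.80, Parp9 -2.19 and -1.81, and Trim30a -2.40 and -1.67. Signals at the floor make those of Fcgr3, the irradiated one of C3ar1 and the unirradiated one of Trim30a bounds. Lgals3bp, a secreted glycoprotein, read 3452 and 3332 in Wip1+/+, and 836 and 755 with the Wip1-/- label. Ifi202b, also interferon-inducible, went the other way, at least 11.9- and 10.1-fold higher.

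Genes different between the genotype labels in both pairs of arrays, 239 of those placed on the genome, may in part reflect strain DNA that travelled with the targeted gene. In a window of Ppm1d and the 100 measured genes on each side of it on chromosome 11, 7 were among them, or 3.48%, against 2.05% elsewhere. Windows of that size had a median of 1.99%, and the central 95% of them ended at 4.48%, so the test neither excludes nor singles out this region. Blocks of strain DNA elsewhere in the genome are a further hypothesis. There were 132 pairs of such genes within 20 measured genes of each other, against a median of 97 and a range of 79 to 117 for the central 95% of random placements. Neighbouring families that are regulated together, such as the Ms4a6 and Ccl clusters, would also give such pairs, so the test does not set strain DNA apart from them. Whether a probe mismatch between strains could give ratios as wide as those of Rpgrip1, Cap1 and Erdr1 was not tested on sequence.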
